A study of Escherichia coli with 8 samples.

How the data were processed

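Ribosome footprints and mRNA of wild-type and EF4-deleted *E. coli*, both under 0.2 µg/ml tellurite, were measured in 8 libraries, 2 per strain and kind. The authors deposited RPKM values for 4760 genes in 2 tables, per the file headers. Per the submitters' processing notes Bowtie2 2.2.9 was used. The genome build, annotation, counting tool and the reads that make up the scaling total are not given in the sources used here. Genes carry a running number and a product name, with no symbol or locus tag. Of the product names, 2913 occur once. Genes are therefore named by product, those with a repeated name also by number, and no coordinates are given. Values of the near-identical EF-Tu genes are uncertain, since it is not given how reads that fit both were counted.

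Everything from here on was computed from the deposited RPKM values. Where a product name holds a symbol of the MG1655 reference gene table (assembly ASM584v2), that gene's length was used to find the RPKM value of 1 read in each library. Between 92.0% and 94.5% of the low values (under 50 reads) of those genes were whole within 0.01. The steps gave each library's total. Lengths of all 4719 genes with any reads followed as the reference length (858 genes) or otherwise the smallest length that made all libraries' reads whole, which can be too short for genes with few reads. The other 41 genes were at 0 in every library. Mutant footprint replicate 1 had 177034 reads on listed genes, against 299625 to 515085 in the other footprint libraries, and mRNA libraries had 11389805 to 15925069. Duplicate libraries were looked for by a chi-square test of recovered reads: per degree of freedom it was 3.05 to 12.0 between footprint replicates and 593 to 729 between mRNA replicates, so none agreed within sampling noise.

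Strains were compared with limma 3.58.1 in R 4.3.3, by eBayes with an intensity trend on log2(RPKM + 1), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Fold changes on this scale understate the change of low genes. Footprints and mRNA were fitted apart, each on its 4 libraries and on genes with a mean RPKM of at least 5. Translational efficiency was tested as an interaction in 1 limma model over 8 libraries, on genes that met that mean in both tables, since the deposited values are not counts. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists with at least 5 members tested. The 33 lists, the tests, the naming rule and the first set of other settings below were fixed before the data were examined. List members were matched to product names after the tables were seen, from the names alone. Some lists share members, so their results are not independent. Examples are ElaB (hibernation and general stress) and the DNA-binding starvation protein (OxyR and general stress). The nitrate reductase catalytic subunit is in both the tellurite list and the list of cytochrome oxidases and anaerobic respiration. Lists with fewer than 5 members tested were not tested: cysteine biosynthesis (4 in footprints) and fimbriae (2 in footprints), with 0 members passing, prophage genes (2 in footprints, both passing), and markers deleted in BW25113. By the naming rule, elongation factor 4 and its neighbours are always given, then up to 10 genes per direction with the largest change among those past the threshold with a mean RPKM of at least 20 and values that do not overlap between strains (for translational efficiency, the same sign in both same-numbered replicates). If fewer than 5 pass, the 5 with the smallest p are given, and up to 4 members of each list described.

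The other settings tried were pseudocounts of 0.1 and 5, no filter and a mean RPKM of at least 20, median centring, quantile normalization, replicate number as a block, no trend, a fit over all 8 libraries, an estimated correlation in camera, and each library left out in turn. Scaling to reads on listed genes, voom on recovered reads, centring together with the block, overlaps with the block, gene lists with each library left out, and camera at the preset correlation on the residual degrees of freedom were added after seeing the data. The scaling to listed genes raised footprint values and kept the pseudocount of 1, which therefore weighed less there than in the main fit. The fits were tested on simulated data, reads drawn from wild-type gene shares at the real library totals. In footprints 35.7% of genes changed 4-fold and 100.0% of those changed 16-fold were recovered among 1976 genes, with 3 false calls. In mRNA the shares were 77.4% and 100.0% among 3665 genes, with 6 false calls, and in translational efficiency 27.8% and 91.9% among 1919 genes, with 3. The median error of the 4-fold and 16-fold log2 changes was -0.59 for each in footprints, 0.13 and 0.14 in mRNA, and -0.63 and -0.56 in translational efficiency. In these simulations reads on listed genes made up the real share of each library total, so the downward error in footprints and in the ratio was built in. All genes of a group were given the same dispersion, and replicates were drawn independently. In the real mRNA libraries same-numbered deviations correlated at 0.75 between strains. Recovery and false calls in the real data may therefore differ from these figures.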

Results

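Ribosome footprints and mRNA were measured in *Escherichia coli* BW25113, the parent strain of a genome-wide collection of single-gene deletions, and in JW2553, which lacks the gene for elongation factor 4 (EF4, LepA), a ribosome-bound GTPase. Both strains had been treated with 0.2 µg/ml of tellurite, a toxic oxyanion, and no untreated culture was among the samples. There were 4 groups of 2 libraries each: wild-type footprints, mutant footprints, wild-type mRNA and mutant mRNA. The tables list 4760 genes by product name, with values as RPKM, reads per kilobase of gene scaled to the library total. The steps between low values gave the library totals behind them. These were 1449029 and 1986933 reads for wild-type footprints and 2013980 and 2761856 for mutant footprints. For mRNA they were 11438290 and 15960101 in wild type and 13038008 and 14951772 in the mutant. Reads on the listed genes made up 20.7% and 20.2% of the wild-type footprint totals, and 8.79% and 18.6% of those of mutant replicates 1 and 2. In the mRNA libraries that share was 99.6% to 99.9%. The median gene therefore had 3 to 11 footprint reads and 192 to 295 mRNA reads. Nothing in the labels says that the replicates were separate cultures, so p-values carry no more than the spread between these samples, which may be technical. In footprints limma's prior degrees of freedom were infinite, so each gene's own spread was replaced by the trend over genes. The SE and p-value of a footprint change therefore do not measure how far that gene's replicates lay apart. In mRNA the prior degrees of freedom were 3.37 beside 2 residual ones. Means are given ± SD over 2 libraries and log2 changes, mutant minus wild type on the log2(RPKM + 1) scale, ± SE.

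The deleted gene was checked first. Elongation factor 4 had footprint values of 82.0 and 88.6 RPKM in wild type and 0.276 and 0.603 RPKM in the mutant, where they rested on 1 and 3 reads. Its mRNA was at 424 and 411 RPKM in wild type and 5.24 and 13.7 RPKM in the mutant. The log2 changes were -5.91 ± 0.86 in footprints (limma, adjusted p = 1.84e-08) and -5.45 ± 0.57 in mRNA (limma, adjusted p = 0.0276). Of the 11 genes of the EF4 locus tested, the GTPase Era, a ribosome assembly factor, also fell in footprints, by 2.60 ± 0.85 (adjusted p = 0.0270), while its mRNA change was -1.15 ± 0.42 (adjusted p = 0.200). The latter passed with replicate number as a block (adjusted p = 0.000213, over all settings tried 0.000139 to 0.670). Without wild-type replicate 1 or 2 or mutant replicate 1 the footprint change of elongation factor 4 was -5.97, -5.86 and -5.75, and that of Era -2.63, -2.56 and -1.82. These fits leave a lone library in a group and too few degrees of freedom to judge by a threshold. The signal peptidase encoded next to EF4 did not pass in footprints (-0.65 ± 0.88, adjusted p = 0.696) or in mRNA (0.16 ± 0.42, adjusted p = 0.870). No other neighbour passed over all genes without a block. Footprints of ribonuclease 3 lay at 50.7 and 62.1 RPKM in wild type and 7.29 and 18.1 in the mutant. Those of RseA lay at 55.1 and 75.0 RPKM in wild type and 122 and 369 in the mutant. Adjusted over the list alone 3 locus genes fell and 0 rose in footprints. With the block 4 of the 11 were higher and 4 lower in mRNA.

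The first comparison asked which genes carried more or fewer ribosome footprints in the mutant under tellurite. Genes of motility led the genes that were higher. Flagellin, the filament subunit, went from 56.9 ± 58.9 to 1665 ± 818 RPKM, a log2 change of 5.28 ± 0.83 (adjusted p = 9.35e-08). The chemotaxis coupling protein CheW rose by 5.70 ± 0.85, and the anti-sigma-28 factor FlgM by 5.63 ± 0.85, from 0 and 14 and from 0 and 8 reads in wild type. L-asparaginase rose from 13.5 ± 11.6 to 621 ± 313 RPKM, and a gene annotated malate dehydrogenase (gene2014, a product name that occurs more than once) from 5.0 ± 0.787 to 271 ± 153 RPKM. Protein FlxA, a dimethylsulfoxide reductase, outer membrane protein W, a two-component system response regulator and the hypothetical protein gene1114 completed the 10 largest increases, with log2 changes from 4.25 to 5.19. In wild type FlxA and the dimethylsulfoxide reductase each had 0 and 2 reads, the response regulator 2 and 7, and gene1114 0 and 5. Outer membrane protein W had 77 and 140. The size of an increase from so few wild-type reads depends on the pseudocount. After elongation factor 4, the iron-sulfur subunit of formate dehydrogenase-O fell most, from 40.7 ± 4.65 to 0.401 ± 0.567 RPKM. The small heat-shock chaperone IbpB fell from 199 ± 18.3 to 9.91 ± 7.47 RPKM, inositol monophosphatase from 154 ± 8.43 to 11.9 ± 15 RPKM and a glucohydrolase from 188 ± 14.5 to 14.6 ± 10.9 RPKM. The Bor lipoprotein homolog of prophage DLP12, the S12 methylthiotransferase accessory factor YcaO, an acid-inducible outer membrane protein, a DEAD/DEAH box RNA helicase and the 23S rRNA methyltransferase RlmH were also among the 10 largest decreases, with log2 changes from -4.13 to -3.71. In the mutant the formate dehydrogenase-O subunit had 0 and 2 reads, RlmH 0 and 10, and the acid-inducible protein 2 and 7. The Bor homolog had 2 and 18, IbpB 4 and 18, YcaO 6 and 32, and inositol monophosphatase 2 and 50. The helicase had 9 and 104 and the glucohydrolase 23 and 102. The size of a fall to so few reads depends on the pseudocount too.

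In all, 132 of 2215 genes tested were higher and 127 lower in the mutant (limma, adjusted p under 0.05). The median gene changed by -0.38, and by 0.26 after each library was scaled to its reads on listed genes. It changed by 0.17 without mutant replicate 1, by -1.01 without mutant replicate 2, and by -0.50 and -0.19 without wild-type replicates 1 and 2. That scaling, chosen after seeing the data, called 478 genes higher and 237 lower, so the share of higher calls went from 51.0% to 66.9%. Voom on the recovered reads called 596 and 315, of which 65.4% were higher, and median centring 423 and 470. Calls varied widely with a library left out, where fewer than the 2 residual degrees of freedom of the full fit remain. Even elongation factor 4 lost its call without wild-type replicate 1 or 2 or mutant replicate 1, though its size held. Calls lost in such fits therefore do not by themselves show that a result rests on a single library. Sizes of some increases did move. Without wild-type replicate 1 CheW, FlgM, flagellin and gene1114 rose by 3.75, 3.70, 3.97 and 2.46. Without wild-type replicate 2 flagellin and gene1114 rose by 6.59 and 6.05. Malate dehydrogenase gene2014 moved less (5.25 and 5.52). CheW, FlgM and gene1114 did not pass without mutant replicate 2 (adjusted p = 0.0635, 0.0670 and 0.0974), nor RlmH when scaled to reads on listed genes (0.0783). Over all settings tried the adjusted p of these 4 ran from 1.37e-12 to 0.991.

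**Figure D1:**
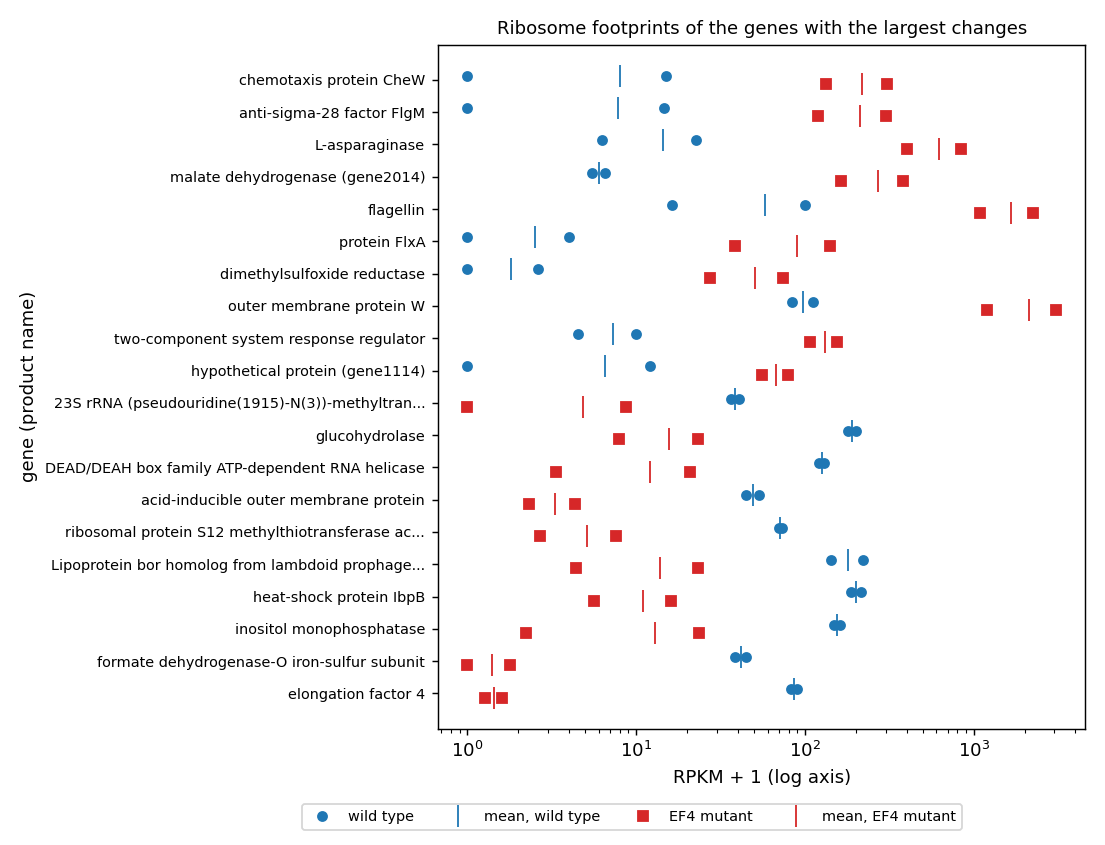
Footprint values of the 10 genes with the largest increases and the 10 with the largest decreases, as RPKM + 1 on a log axis, with a circle or square per library (2 per strain) and a vertical bar at each mean. Flagellin lies at 15.2 and 98.5 RPKM in wild type and at 1087 and 2243 RPKM in the mutant.

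Among 32 proteins of the 50S subunit, 16 fell and 0 rose over all genes tested (25 fell when adjusted over the list alone), with a list median of -2.14. L20 went from 2690.1 ± 816 to 415 ± 297 RPKM. Of 21 proteins of the 30S subunit, 12 fell (20 adjusted over the list alone), with a median of -2.25, and S21 went from 1768 ± 61.8 to 365 ± 299 RPKM. The medians of the 2 lists were -1.03 and -1.0 with quantile normalization, and -1.46 and -1.57 scaled to reads on listed genes. With replicate number as a block 6 proteins of 50S and 3 of 30S fell, and with no filter on low values 8 of the 16 calls and 4 of the 12 were kept. With an estimated correlation camera called neither list (adjusted p = 0.980 for each). Of 15 translation factors, 4 fell (13 adjusted over the list alone). They were initiation factor IF-1 (-3.52 ± 0.83), TypA (-3.54 ± 0.85), release factor 3 (-3.21 ± 0.85) and elongation factor G (-2.38 ± 0.80); the near-identical EF-Tu genes in that list are uncertain. Of 18 ribosome assembly factors 5 fell (9 adjusted over the list alone), and of 23 aminoacyl-tRNA synthetases 3 fell (9 adjusted over the list alone). Iron-sulfur cluster assembly held 5 genes that fell and 1 that rose among 10 (6 and 1 adjusted over the list alone), with the cysteine desulfurase IscS down from 353 ± 41.7 to 41.6 ± 33.4 RPKM and SufA up by 2.68 ± 0.90. Of 5 genes of branched-chain amino acid synthesis 2 fell (4 adjusted over the list alone), among them ketol-acid reductoisomerase (-2.97 ± 0.85). Elongation factor G did not pass with the block or no filter (adjusted p = 0.0650 and 0.0588, over all settings tried 9.63e-06 to 0.991). SufA did not pass in 4 settings with all libraries (0.0622 to 0.109) or without mutant replicate 2 (0.249), with 0.000909 to 0.991 over all tried. None of these 5 further lists was called with an estimated correlation (adjusted p = 0.980 for each).

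Of 47 flagella and chemotaxis genes 20 rose and 0 fell (29 and 0 adjusted over the list alone), with a median of 2.31 against -0.38 for all genes and an adjusted p of 0.980 with an estimated correlation. Scaled to reads on listed genes the list median was 3.26. Of 16 genes of the general stress regulon of RpoS, the stationary-phase sigma factor, 4 rose (9 adjusted over the list alone), including CsiD by 3.69 ± 0.85 and the osmotically inducible lipoprotein E by 2.66 ± 0.85. Ribosome hibernation and rescue had 4 genes of 9 that rose (5 adjusted over the list alone). They were ribosome-associated inhibitor A, which went from 252 ± 131 to 2669 ± 1407 RPKM, ribosome modulation factor (3.16 ± 0.85), the stationary-phase-induced ribosome-associated protein (2.59 ± 0.85) and ElaB (2.40 ± 0.85). Cytochrome oxidases and anaerobic respiration had 3 of 18 (8 adjusted over the list alone), namely the nitrate reductase catalytic subunit, dimethyl sulfoxide reductase subunit B and the nitrate-inducible formate dehydrogenase iron-sulfur subunit. Camera with its preset correlation placed these 4 lists higher, and 50S, 30S, translation factors, assembly factors, synthetases, iron-sulfur assembly and branched-chain synthesis lower, with adjusted p from 2.16e-22 to 0.0209. In a fit over all 8 libraries ElaB and dimethyl sulfoxide reductase subunit B did not pass (adjusted p = 0.184 and 0.0530), the latter nor with no filter (0.0513), with 2.10e-06 to 0.991 over all settings tried for both. None of these calls held with an estimated correlation (adjusted p = 0.980 for each). That form of camera tests on the 2 residual degrees of freedom, on which no list passed at the preset correlation either (smallest adjusted p = 0.218). The estimated correlations of the 11 lists were 0.667 to 0.970. The sign of each of these 11 medians was the same under median centring, quantile normalization and scaling to reads on listed genes. The hibernation and rescue call was lost with that scaling (adjusted p = 0.0747, over all settings tried 0.00530 to 0.980), and without wild-type replicate 1 or 2 or mutant replicate 1 (0.0574, 0.0532 and 0.0894). The branched-chain call was lost without wild-type or mutant replicate 2 (adjusted p = 0.116 and 0.106, over all settings tried 0.00872 to 0.980).

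**Figure D2:**
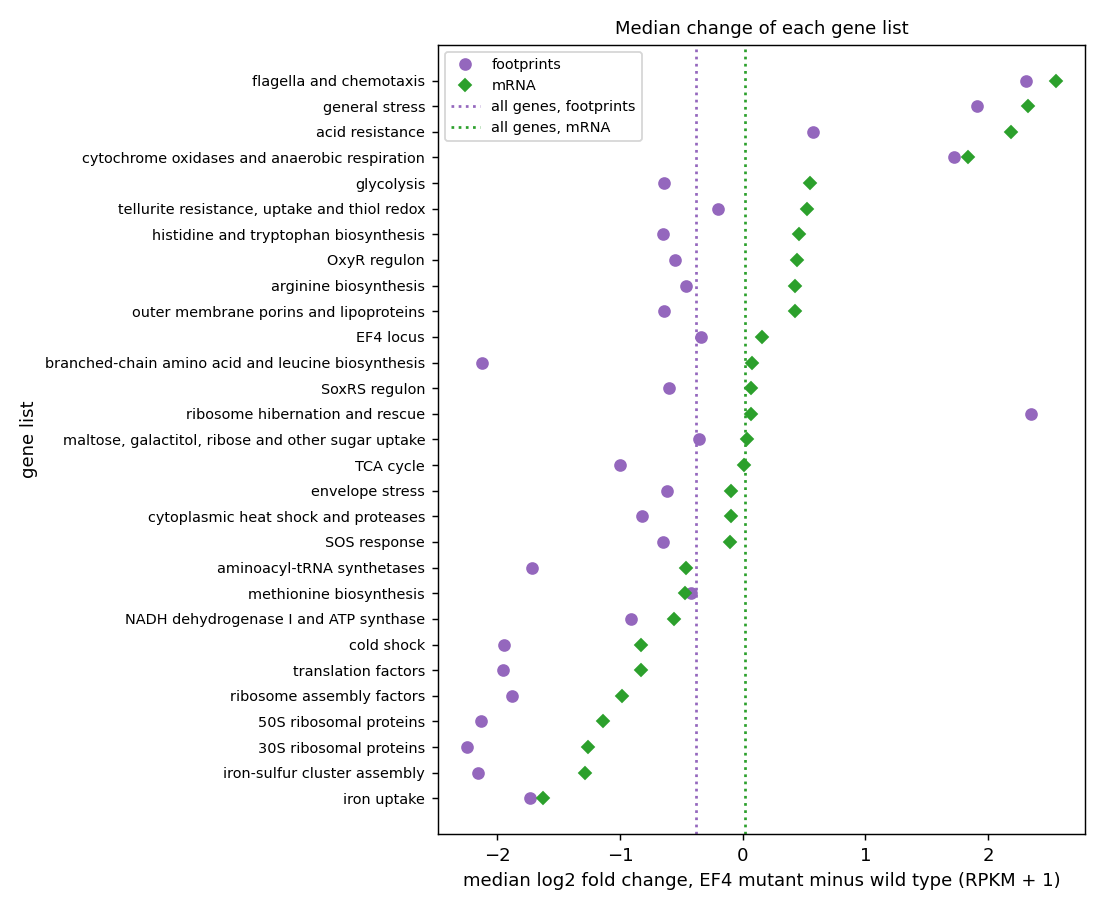
Median log2 fold change of each gene list, mutant minus wild type on the log2(RPKM + 1) scale, with circles for footprints, diamonds for mRNA and dotted lines at the median of all genes tested (-0.38 for footprints, 0.022 for mRNA). Flagella and chemotaxis lie at 2.31 and 2.56, and 50S ribosomal proteins at -2.14 and -1.14.

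The second comparison asked which transcripts differed in level between the strains. Malate dehydrogenase gene2014 rose from 19.7 ± 5.07 to 3513 ± 1254 RPKM, a log2 change of 7.38 ± 0.47 (adjusted p = 0.0276). L-asparaginase rose by 6.33 ± 0.69 and flagellin by 6.26 ± 0.64, the latter from 197 ± 152 to 12810.3 ± 116 RPKM. The flagellar brake protein YcgR rose by 5.81 ± 0.41, CheW by 5.62 ± 0.85 and the chemotaxis kinase CheA by 5.39 ± 0.49. Aldehyde ferredoxin oxidoreductase, dimethyl sulfoxide reductase subunit A and the hypothetical proteins gene1873 and gene2147 rose by 5.31 to 5.43. All 9 genes that passed downward met the rule for naming. Besides elongation factor 4 they were the Bor lipoprotein homolog (-4.75 ± 0.49) and a murein endopeptidase of prophage DLP12 (-4.68 ± 0.54), the iron-sulfur (-4.72 ± 0.70) and cytochrome b556 (-4.37 ± 0.49) subunits of formate dehydrogenase-O, and the hypothetical protein gene4839 (-3.97 ± 0.51). The others were the glucohydrolase (-3.70 ± 0.50), a protease (-2.85 ± 0.43) and IscS, which fell from 998 ± 261 to 146 ± 13.2 RPKM.

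In mRNA 79 of 3731 genes were higher and 9 lower (limma, adjusted p under 0.05). With replicate number as a block the counts were 883 and 700, and 753 and 945 with median centring as well. Fitting a block leaves fewer than the 2 residual degrees of freedom of the full fit. Calls made with it lean mostly on the spread pooled over genes. The mRNA columns of replicates 1 and 2 are written with up to 15 and 17 digits, which sets the numbers apart within the table. With a library left out, fewer than the 2 residual degrees of freedom of the full fit remain. Elongation factor 4 itself lost its call without wild-type replicate 1 or 2, at changes of -5.42 and -5.47. Calls lost in such fits therefore do not show that a result rests on a single library. CheW, the iron-sulfur subunit of formate dehydrogenase-O, the protease and IscS did not pass with no filter, no trend, quantile normalization or voom, nor gene4839 and the glucohydrolase with no trend or quantile normalization (adjusted p = 0.0502 to 0.0694). The protease did not pass without mutant replicate 1 or 2 (0.0561 and 0.0624), nor IscS without mutant replicate 2 (0.0803), and over all settings tried the adjusted p of these 6 genes ran from 1.78e-59 to 0.246.

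**Figure D3:**
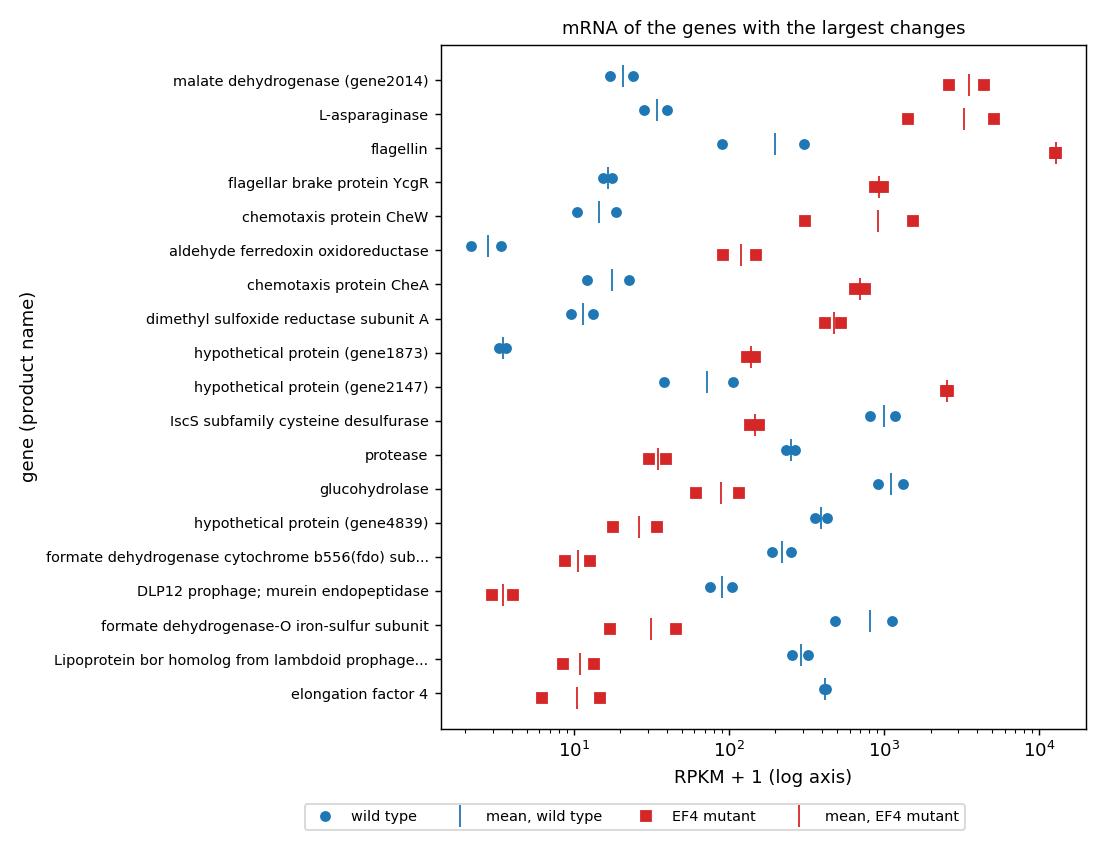
mRNA values of the genes with the largest changes, 10 higher and 9 lower in the mutant, as RPKM + 1 on a log axis, with a circle or square per library (2 per strain) and a vertical bar at each mean. Flagellin lies at 12728 and 12892 RPKM in the mutant.

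Flagella and chemotaxis held 14 of the genes that rose among its 50 members, with 0 that fell (42 and 0 adjusted over the list alone), and a median of 2.56. The filament cap protein, flagellar hook-associated protein 2, rose by 5.0 ± 0.48. In the general stress list 3 of 17 rose (11 adjusted over the list alone): CsiD from 13.6 ± 9.76 to 425 ± 69.4 RPKM, the DNA-binding starvation protein from 391 ± 98.1 to 3171 ± 667 RPKM, and catalase HPII by 3.08 ± 0.47. Of 27 genes of cytochrome oxidases and anaerobic respiration 2 rose and 0 fell (13 and 3 adjusted over the list alone), the iron-sulfur and C subunits of fumarate reductase, each by 2.68. With median centring neither passed (adjusted p = 0.0668 and 0.0716), nor did catalase HPII (0.0509). With no trend 7 of the 14 flagella calls and none of those 3 general stress and 2 fumarate reductase calls were kept, and with quantile normalization 7, 1 and 0. Without mutant replicate 2 neither fumarate reductase gene passed (0.0803 and 0.0823), nor catalase HPII without mutant replicate 1 or 2 (0.0967 and 0.0803), and over all settings tried the adjusted p of these 3 genes ran from 1.41e-14 to 0.226. Ribosome-associated inhibitor A rose by 4.09 ± 0.48 and was the 1 gene of 10 to pass among hibernation and rescue genes (2 adjusted over the list alone); it did not pass with no trend (adjusted p = 0.0575, over all settings tried 9.66e-24 to 0.161). None of the 7 acid resistance genes passed (2 adjusted over the list alone), and their median was 2.19. Without a replicate block no 50S, 30S, translation factor, assembly factor or synthetase gene passed in mRNA, where the list medians were -1.14, -1.26, -0.83, -0.98 and -0.46 (4 genes of 30S and 1 translation factor fell when adjusted over the list alone, and 0 of the other 3 lists). With the block 29 of 32, 21 of 21, 11 of 15, 12 of 19 and 11 of 23 of them were lower, and 0, 0, 1, 2 and 2 were higher. These block calls and those that follow rest on fewer residual degrees of freedom, as given above. The block also called 46 of 50 flagella and chemotaxis genes, 16 of 17 general stress genes and 4 of 7 acid resistance genes higher, and none of these lower. With the block 18 of 27 genes of cytochrome oxidases and anaerobic respiration were higher and 4 lower. Of 10 hibernation and rescue genes 4 were higher and 1 lower with it. Without a block 1 of 13 iron-sulfur assembly genes and 1 of 7 prophage genes fell (3 and 2 adjusted over the list alone). Of 23 iron uptake genes and 22 of NADH dehydrogenase and ATP synthase 0 passed, also over each list alone. Only 7 of the 54 prophage genes fixed for that list were tested. With the block 9 of 13 in iron-sulfur assembly were lower and 1 higher. In iron uptake 15 of 23, in NADH dehydrogenase and ATP synthase 15 of 22 and in prophage genes 3 of 7 were lower with it, and 0 higher. Camera placed flagella, general stress, cytochrome oxidases and anaerobic respiration (1 list), and acid resistance higher. It placed those 5 lists, iron-sulfur assembly (median -1.29), iron uptake (-1.63), NADH dehydrogenase and ATP synthase (-0.56) and prophage genes (-1.09) lower, with adjusted p from 3.90e-22 to 0.0444 over the 13 lists. None held with an estimated correlation (adjusted p = 0.352 to 0.618), but on the 2 degrees of freedom of that test none passed at the preset correlation either (smallest adjusted p = 0.247). The estimated correlations of the 13 lists were -0.131 to 0.684. The synthetase call was lost with median centring (adjusted p = 0.0502, over all settings tried 0.0131 to 0.373), and without wild-type replicate 1 or mutant replicate 1 or 2 (0.289, 0.162 and 0.0881). Without wild-type replicate 1 the iron-sulfur and acid resistance calls were lost too (adjusted p = 0.0505 and 0.0504), the latter also without mutant replicate 1 (0.0761), with ranges of 0.000333 to 0.352 and 0.0143 to 0.353 over all settings tried.

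The third comparison asked whether footprints changed apart from mRNA, as the change in translational efficiency, the ratio of footprint to mRNA. Of 2174 genes, 0 were higher and 1 lower (limma interaction, adjusted p under 0.05), with 21 at an unadjusted p under 0.05; voom on recovered reads called 0, with 32 at an unadjusted p under 0.05. With replicate number as a block 12 were higher and 3 lower, and with centring and the block together 5 and 1. The gene called was the hypothetical protein gene2147, named here after its values were seen. Its ratio fell by 7.23 ± 1.20 (adjusted p = 0.0148), on 1 and 3 footprint reads in wild type and 0 and 2 in the mutant, and it did not pass after median centring (adjusted p = 0.417). As fewer than 5 genes passed in each direction, the 5 with the smallest p are given, none of which passed without a block (adjusted p = 0.967 for each). Upward they were ribosome modulation factor (4.74 ± 1.29), the small protein MntS (3.37 ± 1.02), the leader peptides of the IlvGMEDA (3.83 ± 1.30) and IlvBN (2.74 ± 1.01) operons and lipoprotein NlpI (2.44 ± 0.94). Downward they were the hypothetical proteins gene104 (-3.01 ± 1.00) and gene2026 (-2.28 ± 0.97), ribosomal protein L20 (-2.20 ± 0.96), the tRNA methyltransferase TrmA (-2.44 ± 1.17) and malate dehydrogenase gene2014 (-2.0 ± 0.96). With the block the 5 upward genes and gene104 passed, with adjusted p from 1.70e-09 to 0.0386, and with centring as well MntS, the IlvBN leader and NlpI did (at most 0.0227). Over all settings tried the adjusted p of these 6 genes ran from 1.70e-09 to 1.00. The mutant mRNA replicates of ribosome modulation factor lay at 114 and 9.55 RPKM (250 and 24 reads), and its wild-type footprints rested on 4 and 9 reads. Those of the IlvGMEDA leader lay at 35.6 and 6.76 RPKM (46 and 10 reads), with 1 and 11 footprint reads in wild type. Without mutant mRNA replicate 1 the changes of these genes were 6.47 and 4.95 and passed (adjusted p = 7.64e-05 and 0.0305), and without mutant mRNA replicate 2 they were 3.02 and 2.71 and did not (0.948 for each).

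The median change in translational efficiency over all genes was -0.62, and 0.033 after scaling to reads on listed genes. Without mutant footprint replicate 1 it was -0.049, and without mutant footprint replicate 2 -1.22. Against that median, camera placed aminoacyl-tRNA synthetases (median -1.28), translation factors (-1.23), 50S (-1.03) and 30S (-0.96) ribosomal proteins and glycolysis (-1.07) lower, and iron uptake (0.20) and NADH dehydrogenase and ATP synthase (-0.21) higher, with adjusted p from 3.79e-05 to 0.0386. The last list had a mean of 0.017, so its median differed in sign from its mean and its test, and the median was 0.28 after centring. The 30S list did not pass after centring, scaling to reads on listed genes or with the replicate block (adjusted p = 0.0591, 0.0781 and 0.310), iron uptake after centring or that scaling (0.105 and 0.402), glycolysis after that scaling (0.0508) and 50S with the block (0.133). At a mean RPKM of at least 20 the 30S, glycolysis and NADH dehydrogenase lists did not pass (0.150, 0.150 and 0.208). Over all settings tried the largest adjusted p of these 7 lists was 0.958 to 0.984, and each list but the synthetases lost its call without at least 1 library. No member of these 7 lists passed over all genes, and none when adjusted over the list alone. None of the calls held with an estimated correlation (adjusted p = 0.958), and none on its 4 degrees of freedom at the preset correlation (smallest adjusted p = 0.228); the estimated correlations of the 7 lists were 0.430 to 0.837. The levels themselves, which set tables normalized separately side by side, had a median log2 ratio of -2.15 ± 0.25 in wild type and -2.73 ± 0.85 in the mutant over all genes. Aminoacyl-tRNA synthetases had -1.71 ± 0.07 in wild type and -3.09 ± 0.75 in the mutant, and 50S proteins -2.55 ± 0.15 and -3.56 ± 0.93. The ± of these levels is the square root of the summed variances of the library medians in footprints and in mRNA.

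Changes in footprints and mRNA were close across the 2174 genes in both tables (Pearson's r = 0.83 and Spearman's rho = 0.81 across genes, which are not independent replicates). Of these genes 129 rose in footprints and 72 in mRNA, with 50 in both, where independent lists would share 4.27 (Fisher's exact test, two-sided, p = 1.06e-48). For genes that fell the counts were 125, 7 and 7, against 0.402 (Fisher's exact test, two-sided, p = 1.77e-09). Fisher's test also takes genes as independent, which they are not, so its p-values do not measure the strength of the evidence. No gene was called in opposite directions. With replicate number as a block in mRNA, 684 of these genes rose and 477 fell there, with 117 and 121 also called that way in footprints, against 40.6 and 27.4 for independent lists. Ribosome modulation factor was then called in opposite directions, up by 3.16 ± 0.85 in footprints and down by 1.59 ± 0.58 in mRNA. Its mutant mRNA replicates differed widely, as given above, and the fall in mRNA rests on mutant replicate 2. With the block in both tables the IlvGMEDA leader and gene2147 were as well; these 3 are named after their values were seen, and each rested on few footprint reads in wild type.

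**Figure D4:**
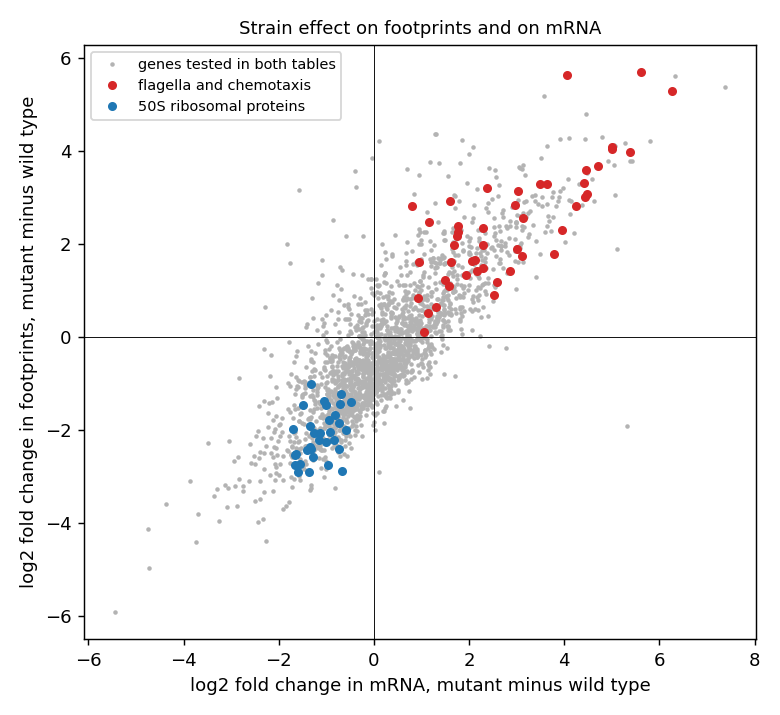
Log2 fold change in footprints (vertical) against log2 fold change in mRNA (horizontal), mutant minus wild type, for the 2174 genes tested in both tables, with flagella and chemotaxis genes in red and 50S ribosomal proteins in blue. The first list lies at the upper right and the second at the lower left, with r = 0.83 over all genes.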

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

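Scaling to reads on listed genes, voom, centring with the replicate block, overlaps with the block, lists with a library left out, and camera on the residual degrees of freedom were chosen after seeing the data. The scale of the footprint libraries, the replicate number and single libraries limit the counts. In simulated reads at the real totals, 27.8% of 4-fold and 91.9% of 16-fold changes in translational efficiency were recovered. Those reads had the same dispersion for all genes of a group and independent replicates, so real recovery may differ. In footprints, genes higher numbered 61 at a mean RPKM of at least 20 (fewer genes tested), and genes higher and lower numbered 423 and 470 with median centring, 444 and 434 with quantile normalization, 223 and 201 with the replicate block, 478 and 237 scaled to reads on listed genes, 596 and 315 with voom, and 483 and 534 with centring and the replicate block together. Leaving out a library gave 0 to 76 higher and 0 to 528 lower. In mRNA, higher and lower were 27 and 4 with quantile normalization, 883 and 700 with the replicate block, 28 and 4 with no trend, 753 and 945 with centring and the replicate block, and 187 and 43 in a fit over all 8 libraries. Genes higher in mRNA were 46 with no filter and 48 with voom. Leaving out a library gave 0 to 96 higher and 0 to 27 lower. For translational efficiency the replicate block gave 12 and 3, centring with the replicate block gave 5 higher, and the 1 lower gene became 0 with a pseudocount of 0.1, no filter, a mean RPKM of at least 20, median centring, quantile normalization, no trend, scaling to reads on listed genes or voom. Leaving out a library gave 0 to 3 higher and 0 to 2 lower. With a library left out, the lone sample of its group is assumed to vary like the others, and fewer residual degrees of freedom remain. Lost gene calls, and upper ends of adjusted p ranges that come from these fits, do not by themselves show that a result rests on a single library. Fits with the replicate block also keep fewer residual degrees of freedom than the main fits. Calls gained with the block, and lower ends of ranges that come from it, do not show a better supported result. Same-numbered libraries shared deviations in mRNA (correlation 0.75 across genes) and little in footprints (0.13), and the labels do not say that the numbers pair samples.

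Camera called 0 lists in either direction with an estimated correlation in each comparison, and 0 at the preset correlation on the same 2 or 4 residual degrees of freedom. Footprint lists were 3 to 4 higher and 7 to 9 lower, and mRNA lists 3 to 4 and 7 to 9, with a library left out. Lists higher in translational efficiency (2) were 1 at a mean RPKM of at least 20, with median centring or scaled to reads on listed genes, and 0 to 4 with a library left out. Lists lower (5) were 3 at a mean RPKM of at least 20, with the replicate block or scaled to reads on listed genes, and 3 to 6 with a library left out. The wild-type median ratio over all genes moved to -1.89 with a pseudocount of 5.

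Of the mRNA changes of named genes, 6 lost their calls with quantile normalization, 6 with no trend, 4 with voom, 4 with no filter and 1 with a pseudocount of 5. Among named genes, changes of sign fell on genes of the EF4 locus that had not passed. In footprints sigma-E became 0.15 with median centring, alone or with the replicate block, 0.16 with quantile normalization, 0.63 scaled to reads on listed genes and 0.63 with voom. RseC became 0.40 and 0.43, pyridoxine 5'-phosphate synthase 0.32 and 0.38, and holo-ACP synthase 0.26 and 0.045 under the last 2 settings. In mRNA the signal peptidase became -0.043 with median centring, alone or with the block, and -0.16 with quantile normalization. The translational efficiency change of elongation factor 4 became 0.88 with a pseudocount of 5, 0.033 with median centring, alone or with the block, and 0.23 with quantile normalization, and that of RseB 0.062 with voom. With a library left out, changes in footprints ran from -0.57 to 0.49 for ECF RNA polymerase sigma-E factor, -0.66 to 1.15 for sigma-E factor regulatory protein RseB, -0.85 to 0.41 for SoxR reducing system protein RseC, -1.13 to 0.45 for pyridoxine 5'-phosphate synthase. With a library left out, changes in mRNA ran from -0.69 to 0.081 for SoxR reducing system protein RseC, -0.14 to 0.45 for S26 family signal peptidase. With a library left out, changes in translational efficiency ran from -0.42 to 1.17 for anti-sigma-E factor RseA, -1.59 to 0.22 for sigma-E factor regulatory protein RseB, -0.54 to 0.72 for SoxR reducing system protein RseC, -1.09 to 0.15 for elongation factor 4. The cause of these changes was not tested.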

Other observations

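The tests of scaling, of the left-out library, of a global drop in the ratio and of a batch by replicate number were chosen only after their results were seen; those of FlhDC and of gene length were written before.

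Camera did not call the lists tied to tellurite (adjusted p = 0.854 in footprints and 0.126 in mRNA), OxyR (0.854 and 0.296) or SoxRS (0.450 and 0.848). Their footprint medians of -0.20, -0.55 and -0.60 were 0.46, 0.11 and 0.021 when scaled to reads on listed genes. Of the genes of tellurite resistance, uptake and thiol redox, 1 of 12 rose in footprints (1 adjusted over the list alone), the nitrate reductase catalytic subunit by 3.02 ± 0.93, and 0 of 15 passed in mRNA (3 adjusted over the list alone; 7 higher and 2 lower with replicate number as a block). In the OxyR regulon catalase-peroxidase rose in footprints from 34 ± 1.53 to 198 ± 79.1 RPKM, and the DNA-binding starvation protein rose in mRNA, though not with quantile normalization or no trend (adjusted p = 0.0569 and 0.0649, over all settings tried 3.48e-13 to 0.206). In the SoxRS regulon, the response to superoxide and redox-cycling agents, manganese superoxide dismutase fell in footprints from 702 ± 339 to 108 ± 76.2 RPKM and the regulator SoxS from 203 ± 109 to 41.3 ± 30.2 RPKM. In mRNA neither passed without a block (adjusted p = 0.0986 and 0.0812), and both fell with it (9.80e-07 and 1.88e-06), while pyruvate dehydrogenase [ubiquinone] rose by 3.07 ± 0.47. The last did not pass in 5 other settings with all libraries (adjusted p = 0.0510 to 0.0609) or without mutant replicate 1 or 2 (0.0889 and 0.0693), with 5.38e-16 to 0.211 over all tried. Of the SOS genes 0 of 10 passed in footprints and 0 of 16 in mRNA (limma), with 0 and 0 adjusted over the list alone; with the block 1 was higher in footprints and 2 lower in mRNA. Of 9 cold-shock genes 2 fell and 1 rose in footprints (6 and 1 adjusted over the list alone), with a median of -1.95; camera did not call the list (adjusted p = 0.0515, and 0.980 with an estimated correlation). CspB (-3.42 ± 0.85) and CspG (-3.09 ± 0.85) fell, and CspD, known from stationary phase, rose by 3.59 ± 0.83. In mRNA 0 of 9 fell and 1 rose (1 and 1 adjusted over the list alone), and 6 were lower and 2 higher with the block. The 1 was CspD (2.53 ± 0.37), which did not pass with no filter, median centring, quantile normalization, no trend or voom (adjusted p = 0.0511 to 0.0832) or without mutant replicate 2 (0.0923), with 2.74e-08 to 0.231 over all settings tried.

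Of the flagella and chemotaxis genes 20 of 47 rose in footprints and 14 of 50 in mRNA, and camera did not call the list with an estimated correlation (adjusted p = 0.980 and 0.352), a test in which no list passed. A scale factor moves all genes of a library alike. The list median in mRNA was 2.56 against 0.022 for all genes, which argues against such a factor as the source. Over 3 other scalings the lowest median of the list in mRNA was 2.26. These scalings left the median of all genes in mRNA between -0.18 and 0.020, so that test could hardly have ended otherwise. A higher transcript level of the master regulator FlhDC stays open: the mRNA changes were 0.95 ± 0.51 for FlhD and 1.05 ± 0.54 for FlhC (adjusted p = 0.350 and 0.334; 0.00760 and 0.00570 with the replicate block), and the former lies between the values set beforehand for and against it. Growth stage and strain background are biological differences that these samples do not separate from the deletion, and neither was tested.

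The footprint to mRNA ratio was lower in the mutant over all genes, with a median of -0.62. It was 0.033 once each library was scaled to its reads on listed genes and -0.049 without mutant footprint replicate 1, but -1.22 without mutant footprint replicate 2. Simulated reads with wild-type gene shares at the real totals erred by -0.63 (4-fold changes) and -0.56 (16-fold) in the ratio. They kept the real share of reads on listed genes, so this error was built in and is no test of the cause. Scaling to reads on listed genes would likewise remove most of a shift over all genes whatever its cause. The counting of other reads in the footprint total, in mutant replicate 1 above all, is a candidate explanation that these results do not decide. Fewer ribosomes per transcript throughout the mutant cannot be told apart from it, since every library is scaled to its own total.

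Replicates of the same number deviated together in mRNA, with a correlation of 0.75 between strains. The columns of both numbers also differ in written digits, so a processing batch shared by replicate number is a candidate explanation. Gene length is argued against as its basis: Spearman's rho of the replicate difference with length was -0.066 in wild type and -0.065 in the mutant.

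Of markers deleted in BW25113, beta-D-galactosidase had 0 or 1 footprint reads per library and mRNA values of 3.56 to 9.17 RPKM, and rhamnulose-1-phosphate aldolase had 0 footprint reads and 0.424 to 3.92 RPKM.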
